A study of Homo sapiens with 6 samples.

How the data were processed

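The samples were 6 libraries of total RNA from cultured human nasal airway epithelial cells, 3 from cultures kept in 10 µM Y-27632 for the 8 days of passage 2 and 3 from cultures without it. The series states that treated and untreated samples are paired and the labels give 3 donors, so libraries with the same sample number were taken as a pair from 1 donor. The deposited table holds raw counts, as whole numbers, for 20777 gene symbols in 6 columns. Per the labels, the authors made Ion AmpliSeq Transcriptome libraries, sequenced them on an Ion Torrent Proton and counted uniquely mapping reads per amplicon target with the ampliSeqRNA plugin on genome build hg19. They had removed duplicated target sequences and corrected the bed locations of 166 amplicons. The plugin version is not stated, and positions are not given here because the table holds none. Each gene is read by 1 amplicon, so a change in isoform use or a poorly reading amplicon cannot be told from a change in the gene's level.

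Library totals ran from 9015713 to 23312693 counts. The reads carry no molecular identifiers, so floors cover counting error only. The floor for a group at 0 was 3 counts over the group. Before testing, 78 genes (XIST, Y-linked and HLA genes) were left out, since their levels mark individual people, and 3577 of the remaining genes had 0 counts in all libraries. The low-count filter (filterByExpr by treatment, minimum count 10) kept 12244 genes and left 4878 genes with some counts untested.

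Counts were scaled by TMM factors and fitted with edgeR 4.0.16 in R 4.3.3 by robust quasi-likelihood with donor and treatment as terms. The treatment coefficient (Y-27632 over untreated) was tested by the quasi-likelihood F-test, 2-sided, and p values were adjusted by Benjamini-Hochberg over all tested genes with a threshold of 0.05. The SE of a log2 fold change is its size over the square root of F. The fit had a common biological coefficient of variation of 0.163. CPM values use the TMM-scaled library sizes, except those of olfactory receptor, keratin-associated protein and fibroblast genes in the background check, which use plain totals. Log2 CPM values use a prior count of 2.

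Before the data were examined, 30 gene lists were fixed for actomyosin regulation and signalling, epithelial cell types, differentiation, proliferation, stress, metabolism and other cell types. The 27 with at least 5 tested members were tested with camera at a preset correlation of 0.01 and adjusted over the 27, and again with an estimated correlation and with fry, whose 1-direction p asks whether a list's genes move on balance 1 way and does not compare the list with other genes. The genes named were also fixed by rule: the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 10 CPM and the same sign in all 3 pairs (184 genes were eligible); up to 3 tested members of each list, those with the smallest p; and 3 kinases, PKN2 among them. Not every gene that the rule names is reported. ECM1, GJB6, CLDN7, ALDH1A3, TP63, KRT17, DSG1, PTPRC, CXCL5, COL22A1, ZEB1, ZEB2, SNAI1, TWIST1, TWIST2, PRRX1 and the fibroblast genes COL1A2, COL3A1, DCN and LUM were added after their values were seen. So were KRTAP2-3 and SLC3A2, SLC7A1, NUPR1, CYP26A1, DHRS3 and RARRES3, the last 6 from amino acid response and retinoid lists drawn up later.

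The fit was tested on simulated data of the same depth and design with 200 changed genes. With dispersions that follow the trend, 77.8% of genes changed 2-fold and 98% of those changed 4-fold were recovered, and 3.31% of 181 calls were false. With dispersions that scatter from gene to gene, 71.1% and 99.0% were recovered and 9.73% of 185 calls were false, above the nominal rate. In simulated sets the raised list was found and 0 of 20 unchanged lists were called, with either correlation, in data without correlation between genes. The raised list had an adjusted p of 2.0e-90 with the preset correlation and 0.042 with an estimated one. With an estimated correlation camera thus found the raised list only narrowly, and a list it does not call is not shown to be unchanged.

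The alternatives were other scalings (RLE, upper quartile, or without the 20 most abundant genes), no low-count filter, a mean of at least 10 CPM, no donor block, leaving out each donor (both libraries), DESeq2 1.42.0, limma-voom (limma 3.58.1), thinning to the smallest library, a threshold of 0.01 and a glmTreat test against a 1.5-fold change. A filter at the level of the olfactory receptor reads was added after those reads were seen. Sample numbers were checked by correlation of library deviations and by sex-linked transcripts. Libraries were also compared by Spearman correlation of counts over all genes kept before the low-count filter and by principal components of log2 CPM of the tested genes. Figures were drawn with matplotlib 3.10.9.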

Results

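Gene expression was measured in human nasal airway epithelial cells grown from nasal brushings of 3 donors. The cells were expanded by conditional reprogramming, a culture method that combines a layer of irradiated NIH3T3 mouse fibroblasts (feeder cells) with Y-27632, a small-molecule kinase inhibitor. All cultures received 10 µM Y-27632 before passage 2. During passage 2 the cells of each donor were cultured for 8 days either with 10 µM Y-27632 (3 libraries) or without it (3 libraries, called untreated). Each number from 1 to 3 stands for 1 donor and pairs 1 library of each group. The libraries were AmpliSeq amplicon libraries, in which 1 amplicon reads each gene. The untreated libraries of donors 1, 2 and 3 held 12279203, 9015713 and 23312693 counts, and the treated libraries 10820261, 16812280 and 14352117. Genes are given by symbol, the identifier in the count table, which holds no positions.

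Reads on genes that epithelial cells are not known to transcribe differed between the libraries. Of 368 olfactory receptor genes, which encode odorant receptors of sensory neurons, 335 had reads in untreated library 1, 288 in untreated library 2 and 67 in untreated library 3, against 35, 53 and 41 in the treated libraries. Their sum was 409.5, 109.6 and 5.02 CPM (counts scaled to the library total) in the untreated libraries of donors 1, 2 and 3, and 7.77, 6.25 and 5.16 in the treated ones. The 84 genes for keratin-associated proteins, which are structural proteins of hair, gave 83.9, 33.7 and 2.79 CPM untreated and 1.20, 3.69 and 1.39 treated. The 95th percentile of the olfactory receptor genes in untreated library 1 was 2.20 CPM, so levels of a few CPM in that library are near this background. Untreated library 1 also had the most genes detected, 15825, against 14319 to 15020 in the other 5.

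**Figure D1:**
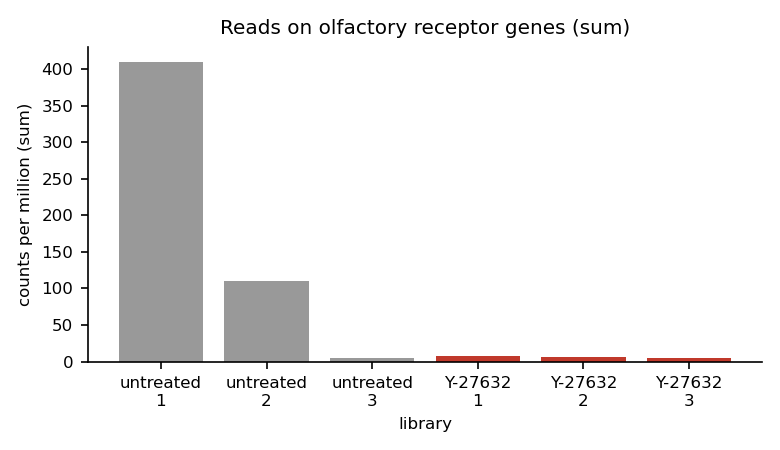
Summed CPM of 368 olfactory receptor genes in each library (bars; grey, untreated; red, Y-27632). Untreated libraries 1 and 2 stood at 409.5 and 109.6, and the other 4 libraries between 5.02 and 7.77.

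The comparison of Y-27632 with untreated cells asks which transcripts differ in these airway progenitor cultures when the inhibitor is kept rather than withdrawn. With Y-27632 the keratins KRT14, KRT5 and KRT16 and the stratified epithelium gene SBSN rose, while the basal marker list was not called (adjusted p = 0.13) and the squamous list held 2 rises and 2 falls. The secretory genes LCN2, WFDC2, MUC1 and MUC4, the defence genes SAA2, C3 and CCL20 and the mesenchymal genes FN1, VIM, MMP9 and TGM2 fell. The secretory, NF-kB and mesenchymal lists that hold these were called with a preset correlation, and each had an adjusted p of 0.41 with an estimated correlation. SBSN, SAA2, FN1 and VIM kept their calls whichever donor was left out, and the others named here lost theirs without donor 2 or donor 3. Of 12244 genes tested, 258 differed at an adjusted p under 0.05 (edgeR, donor as a block): 71 were higher with Y-27632 and 187 were lower. Each of the 258 had the same sign in all 3 pairs. That is no added support, since a test with a donor block favours genes whose pairs agree. The change was at least 2-fold in 44 of the higher and 139 of the lower genes. The number depends on the donors: 449 genes were called without donor 1, 157 without donor 2 and 38 without donor 3, of which 243, 100 and 26 were among the 258. Without the donor block edgeR called 0 genes, with 764 at an unadjusted p under 0.05 (2053 with the block), while with the block DESeq2 called 555 and limma-voom 275.

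**Figure D2:**
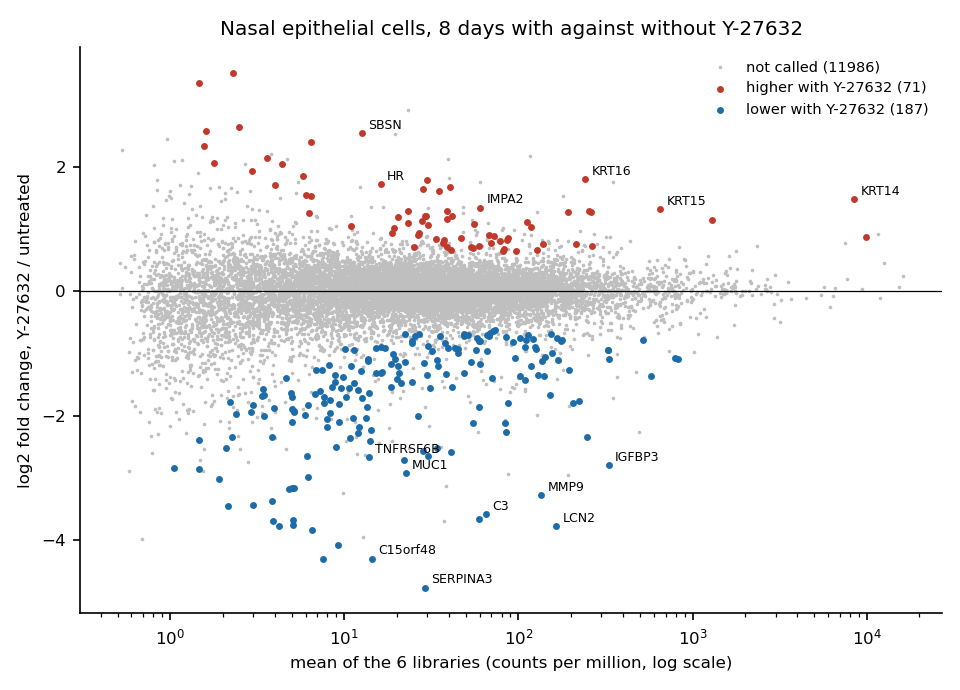
Log2 fold change with Y-27632 against the mean of the 6 libraries in CPM (log scale) for the 12244 tested genes, with 71 higher genes in red, 187 lower genes in blue and the others in grey. The falls reach further than the rises, from -4.76 for SERPINA3 to 2.54 for SBSN among the labelled genes.

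Among called genes with a mean of at least 10 CPM, SBSN had the largest rise. SBSN encodes suprabasin, a protein of differentiating stratified epithelium, and went from 3.81 ± 2.05 CPM untreated to 21.6 ± 8.20 CPM with Y-27632 (mean ± SD, n = 3), a 5.80-fold rise with a log2 fold change of 2.54 ± 0.21 (SE) and an adjusted p of 0.0030. KRT16, a keratin of activated and hyperproliferative epidermis, rose 3.50-fold (from 106 ± 27.9 to 380 ± 149 CPM, adjusted p = 0.026). DMKN, which encodes the epidermal secreted protein dermokine, rose 3.06-fold (adjusted p = 0.011). The basal cell keratins KRT14 and KRT15 rose 2.79-fold and 2.50-fold, and KRT14 reached 12241 ± 5890 CPM from 4733 ± 3405 CPM. The amino acid transporter SLC7A8 rose 3.45-fold and STC2, which encodes the secreted glycoprotein stanniocalcin 2, rose 3.19-fold. The imprinted non-coding RNA H19 (3.12-fold), HR, which encodes the corepressor hairless (3.28-fold), and the inositol phosphatase gene IMPA2 (2.54-fold) completed the 10 largest rises.

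Among the called genes with a mean of at least 10 CPM, the largest fall was that of SERPINA3. It encodes the acute-phase protease inhibitor alpha-1-antichymotrypsin. It went from 55.6 ± 68.3 CPM untreated to 2.33 ± 3.41 CPM with Y-27632, a 27.1-fold fall with a log2 fold change of -4.76 ± 0.31 (SE) and an adjusted p of 0.0023. C15orf48 fell 19.6-fold (from 27.4 ± 18.3 to 1.38 ± 1.14 CPM). LCN2, which encodes the antibacterial iron-sequestering protein lipocalin 2, fell 13.6-fold (from 299 ± 209 to 30.4 ± 38.1 CPM), and the complement gene C3 fell 11.9-fold. TGM2 (transglutaminase 2) fell 12.6-fold, the gelatinase gene MMP9 fell 9.64-fold, the membrane mucin MUC1 7.55-fold, the growth factor binding protein IGFBP3 6.92-fold and the chemokine CCL20 6.56-fold. TNFRSF6B, which encodes a soluble decoy receptor for FAS ligand, fell 6.35-fold. The SDs between donors within a group were as large as the means for several of these genes.

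With 1 donor left out at a time, SBSN, SERPINA3, C15orf48 and TNFRSF6B stayed under an adjusted p of 0.05 in all 3 fits. The other 16 of these 20 genes missed it in at least 1 fit and kept their direction. Without donor 3, KRT16 (0.116), SLC7A8 (0.0502), H19 (0.174), DMKN (0.0719), IMPA2 (0.0527), LCN2 (0.0794), TGM2 (0.0518), C3 (0.114), MMP9 (0.0794), MUC1 (0.101) and IGFBP3 (0.102) missed it, with the adjusted p in brackets. HR (0.160), KRT14 (0.0501), KRT15 (0.154) and CCL20 (0.0589) missed it without donor 2, and STC2 without donor 1 and without donor 2 (up to 0.222).

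**Figure D3:**
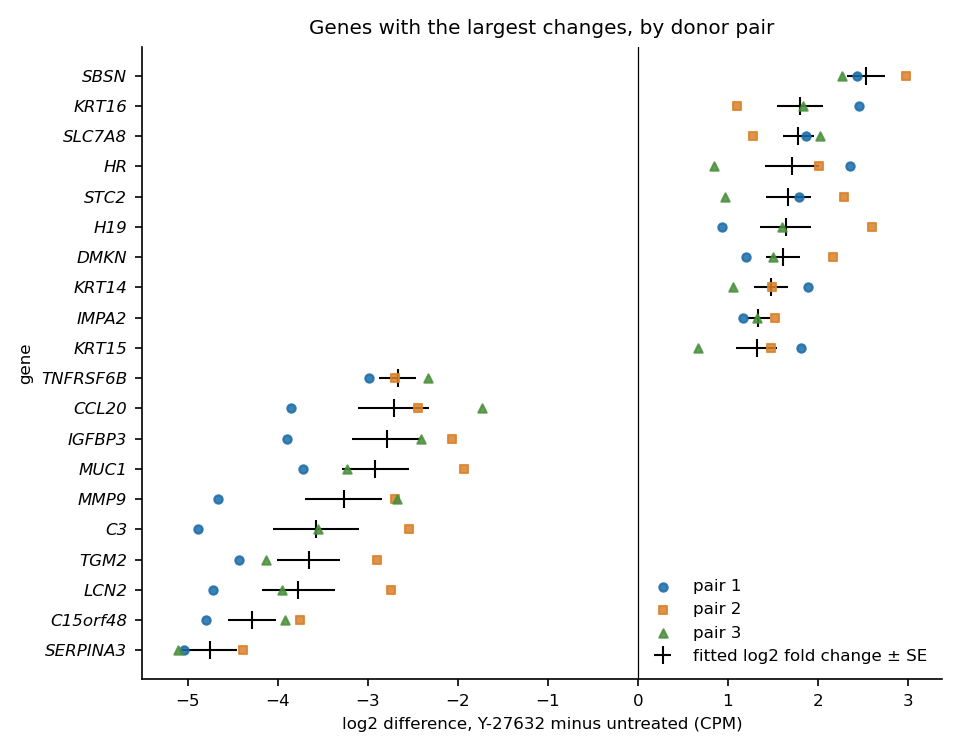
Log2 difference between Y-27632 and untreated cells in each of the 3 pairs (coloured points) and the fitted log2 fold change ± SE (black) for the 10 largest rises and 10 largest falls. The rule that chose the 20 genes required 1 sign in all pairs, and SERPINA3 lies between -5.11 and -4.39 in the 3 pairs.

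Regulators of actomyosin, the contractile apparatus of the cell, changed in few members. Of 33 tested, 0 rose and 2 fell. MYL9, the regulatory light chain of non-muscle and smooth muscle myosin, fell 3.10-fold (adjusted p = 0.0086). The kinase gene PKN2 had a log2 fold change of -0.18 ± 0.12 (SE, adjusted p = 0.51). CDC42BPA, a kinase that acts on myosin light chains, had a log2 fold change of -0.52 (adjusted p = 0.093). Of its members, 3 fell adjusted over the list alone, and the list's adjusted p in the camera set test was 0.058. Of 26 tested targets of SRF and its MRTF cofactors, actin-responsive transcription factors, TAGLN (transgelin) fell 3.28-fold, the other 25 did not pass, and 1 fell adjusted over the list alone; CNN3 and MKL1 stood at -0.50 and -0.43 (log2) and the set's adjusted p was 0.15. Of 22 YAP and TAZ targets, genes that respond to cell tension and density, 1 passed, IGFBP3, and AJUBA (log2 0.55, adjusted p = 0.085) and ASAP1 (log2 -0.48, adjusted p = 0.089) did not. Within the list, 1 rose and 6 fell adjusted over the list alone, and the set's adjusted p was 0.053. MYL9 and TAGLN missed the threshold without donor 3 (adjusted p = 0.0697 for both), as did IGFBP3 (0.102). Without donor 2 the YAP and TAZ list was called (adjusted p = 0.0045, or 0.66 with an estimated correlation), as was the actomyosin list without donor 1 (0.022, or 0.56). With 1 donor left out, too few libraries remain for camera with an estimated correlation to tell lists apart. The secretory list, at 3.2e-31, 1.8e-75 and 1.7e-27 with the preset correlation without donors 1, 2 and 3, had 0.56, 0.66 and 0.65 with an estimated one. Such values, here and below, therefore count neither for nor against a call.

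Basal cell markers, the genes of the progenitor layer of airway epithelium, did not move as a set, while 3 of their keratins rose. Of 21 tested members, KRT14, KRT15 and KRT5 rose and the other 18 did not pass, among them KRT17, the most abundant keratin of the list (log2 0.92, adjusted p = 0.15). KRT5 rose 1.83-fold, from 7169 ± 2615 to 12704 ± 2490 CPM (adjusted p = 0.042). Adjusted over the list alone, 7 rose and 3 fell. The list's median log2 fold change was 0.07 and its adjusted p 0.13. KRT5 missed the threshold without donor 2 or donor 3 (adjusted p up to 0.201), and KRT14 (0.0501) and KRT15 (0.154) without donor 2. TP63, a standard basal cell marker, had 1 read in all 6 libraries, so its level could not be measured.

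Secretory cell markers are the mucins and secreted defence proteins of luminal airway cells. Of the 27 in the list, the 16 with enough reads to be tested all had negative values. Of these, 6 fell and 10 did not pass over all genes, and all 16 fell adjusted over the list alone. WFDC2 fell 6.0-fold (from 69.0 ± 41.0 to 13.3 ± 13.3 CPM, adjusted p = 0.014), LCN2 13.6-fold and the membrane mucin MUC4 5.27-fold (adjusted p = 0.022). The median log2 fold change of the list was -2.0, with -2.83, -1.34 and -2.78 in pairs 1, 2 and 3. The set test called the list at an adjusted p of 1.5e-29 with a preset correlation of 0.01, and the adjusted p was 0.41 with an estimated correlation. Without donor 3 the 3 genes missed the threshold (adjusted p of 0.0776 for WFDC2, 0.0794 for LCN2 and 0.0686 for MUC4). Ciliated cell markers were close to the detection limit: 5 of 28 were tested and 0 passed with edgeR (2 at an unadjusted p under 0.05, 0 with DESeq2 or limma-voom), led by DNAH5 (log2 -1.52, adjusted p = 0.14), DNAH11 (log2 -0.90, adjusted p = 0.27) and CAPS (log2 -0.46, adjusted p = 0.40). Of its members, 1 of the 5 fell adjusted over the list alone, and the set's adjusted p was 0.13. The means of DNAH5 and DNAH11, 1.32 and 1.82 CPM, lie within the level that olfactory receptor genes had in untreated library 1.

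**Figure D4:**
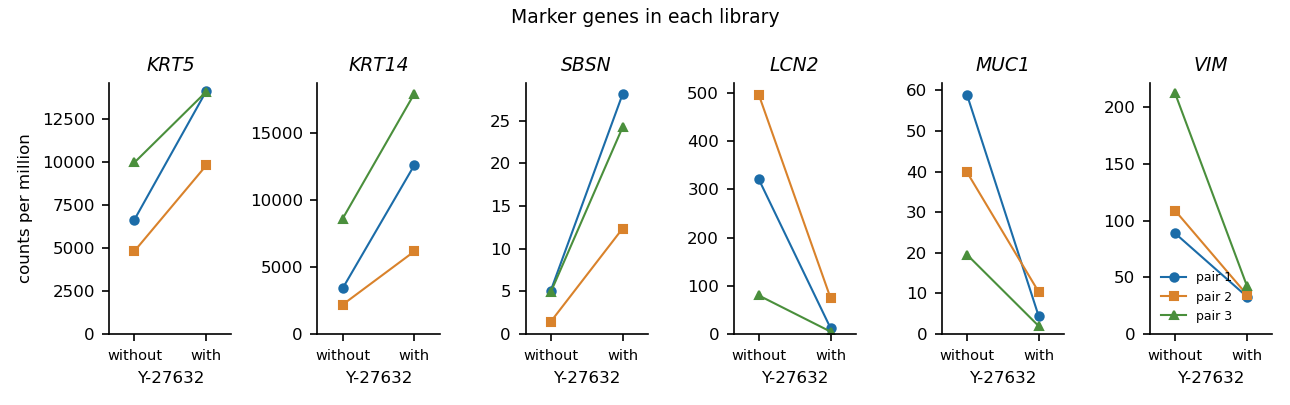
CPM of 6 marker genes in each library, with lines joining the untreated and treated library of a donor and each axis starting at 0. The basal keratins KRT5 and KRT14 and the stratified epithelium gene SBSN are higher with Y-27632 in 3 of 3 pairs, and LCN2, MUC1 and VIM are lower in 3 of 3. All 6 are called genes, and the test with a donor block favours genes whose pairs agree.

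Genes of squamous differentiation and the cornified envelope, the programme of stratified epithelium, went both ways. Of 28 tested members, SBSN and KRT16 rose, the protease KLK7 fell 1.91-fold (adjusted p = 0.031), ECM1, an extracellular matrix protein gene, fell 2.15-fold (adjusted p = 0.038) and 24 did not pass. Within the list, 6 rose and 3 fell adjusted over the list alone. The median log2 fold change was 0.21, with 0.26, 0.67 and -0.41 in pairs 1, 2 and 3, and the set test called the list at an adjusted p of 0.0074 (adjusted p = 0.55 with an estimated correlation). KRT16 missed the threshold without donor 3 (0.116) and KLK7 (up to 0.174) and ECM1 (up to 0.116) without donor 2 or donor 3. DSG1, a desmosomal cadherin of the same list, was too low to be tested, with 0 reads in the untreated libraries and 39, 4 and 63 in the treated libraries of donors 1, 2 and 3. With reads pooled over donors and a floor of 3 counts over the untreated group, this is at least 37.5-fold higher. The bound is at least 23.2-fold without donor 1, 48.1-fold without donor 2 and 11-fold without donor 3. It rests on donors 1 and 3, since the 4 reads of treated library 2 are near the floor and show no rise by themselves.

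Genes of NF-kB signalling and epithelial inflammation had negative values for all 28 tested members. Of these, 9 fell and 19 did not pass over all genes, and 22 fell adjusted over the list alone. The acute-phase genes SAA2 and SAA1, which encode serum amyloid A proteins, fell 19.7-fold (from 14.4 ± 11.9 to 0.681 ± 0.543 CPM, adjusted p = 0.0023) and 13.4-fold (adjusted p = 0.012). TLR2, a receptor for bacterial lipoproteins, fell 3.83-fold (adjusted p = 0.030). The median log2 fold change was -1.57, with -2.37, -1.15 and -0.95 in pairs 1, 2 and 3. The set's adjusted p was 6.6e-30 with the preset correlation and 0.41 with an estimated correlation. SAA2 kept its call without each donor, SAA1 missed it without donor 3 (0.0629) and TLR2 without donor 2 or donor 3 (up to 0.135). Interferon-stimulated genes, which respond to viral infection, had 26 tested members, of which 1 fell, IFI27 (1.89-fold, adjusted p = 0.038), over all genes and 1 adjusted over the list alone. IFITM1 and MX1 had log2 fold changes of -1.27 (adjusted p = 0.14) and -0.78 (adjusted p = 0.18). The median was -0.37, and the set's adjusted p was 0.0034, or 0.41 with an estimated correlation. IFI27 missed the threshold without donor 1 or donor 3 (up to 0.177).

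Mesenchymal transition genes, which mark loss of epithelial character, held 5 that fell among 15 tested: FN1, VIM, MMP2, TGM2 and MMP9. The list had 22 genes, and several of its transcription factors had too few reads to be tested in either group. ZEB2, TWIST1 and TWIST2 had 0 reads in each library, and ZEB1, PRRX1 and SNAI1 had at most 4, 5 and 11 in any library. FN1, which encodes the matrix protein fibronectin, fell 16.8-fold (from 17.3 ± 24.2 to 1.07 ± 1.6 CPM, adjusted p = 0.0030). VIM, the intermediate filament vimentin, fell 3.48-fold (from 137 ± 66.2 to 36.8 ± 5.12 CPM, adjusted p = 0.0082), and the gelatinase gene MMP2 fell 2.47-fold (adjusted p = 0.011). Adjusted over the list alone, 1 rose and 8 fell. The median log2 fold change was -0.37, the set's adjusted p was 7.3e-11 with the preset correlation and 0.41 with an estimated correlation, and fry gave an adjusted p of 0.030. In untreated library 1 FN1 stood at 2.50 CPM, near the 2.20 CPM of the olfactory receptor genes there. FN1 and VIM kept their calls without each donor, MMP2 missed it without donor 2 (0.0667), and TGM2 (0.0518) and MMP9 (0.0794) without donor 3. Of 6 tested fibroblast markers, 0 passed with edgeR (2 at an unadjusted p under 0.05, 1 with DESeq2, 0 with limma-voom), with COL1A1 at a log2 fold change of -0.78 (from 45.3 ± 7.74 to 27.5 ± 11.5 CPM, adjusted p = 0.053), FAP at -1.91 (adjusted p = 0.080) and MFAP5 at 1.17 (adjusted p = 0.30). Of its members, 2 fell adjusted over the list alone, and the set's adjusted p was 0.15. COL1A2, COL3A1, DCN and LUM, also transcripts of human fibroblasts, had at most 6 reads in any library.

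Of 32 tested cell-matrix adhesion genes, 3 fell and 29 did not pass. The integrin subunit ITGB6, which serves to activate TGF-beta, fell 3.38-fold (from 335 ± 150 to 108 ± 79.1 CPM, adjusted p = 0.0084). The integrin-binding adaptor FERMT2 fell 3.48-fold (adjusted p = 0.011) and the integrin subunit ITGB3 13.6-fold (from 7.80 ± 5.89 to 0.678 ± 1.11 CPM, adjusted p = 0.038). Within the list, 1 rose and 4 fell adjusted over the list alone. The median was -0.14 and the set's adjusted p 0.00048, or 0.41 with an estimated correlation. ITGB6 (0.0670) and ITGB3 (0.148) missed the threshold without donor 3, and FERMT2 without donor 2 or donor 3 (up to 0.0852). Of 31 cell-cell junction genes, 2 rose and 3 fell. The desmosomal plakophilin PKP1 rose 2.40-fold (from 152 ± 25.6 to 370 ± 89.4 CPM, adjusted p = 0.015) and the connexin GJB6 rose as well (log2 0.82, adjusted p = 0.038). The tight junction genes OCLN (2.48-fold, adjusted p = 0.017), CLDN4 (3.18-fold, adjusted p = 0.025) and CLDN7 (log2 -1.26, adjusted p = 0.034) fell. Adjusted over the list alone, 9 rose and 7 fell, with a median of 0.06, a mean of -0.07 and a set test pointing up at an adjusted p of 0.88. PKP1 (up to 0.0719) and GJB6 (up to 0.181) missed the threshold without donor 2 or donor 3, OCLN and CLDN4 without donor 3 (0.102 for both), and CLDN7 without donor 1 or donor 3 (0.137 for both).

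Targets of TGF-beta signalling held 1 that rose and 3 that fell among 21 tested. ID3, an inhibitor of differentiation that BMP signals also induce, rose 2.19-fold (adjusted p = 0.012), and INHBA, an activin subunit, fell 3.72-fold (adjusted p = 0.024). The median was -0.28 and the set's adjusted p 0.0019, or 0.48 with an estimated correlation, and 1 rose and 9 fell adjusted over the list alone. Of 20 senescence-associated secreted factors and cell cycle inhibitors, 4 fell, IGFBP3 and the lipoprotein lipase inhibitor ANGPTL4 (2.29-fold, adjusted p = 0.034) among them. Of its members, 1 rose and 10 fell adjusted over the list alone, with a median of -0.73 and an adjusted p of 2.2e-09, or 0.48 with an estimated correlation. ID3 (up to 0.0859), INHBA (up to 0.151) and ANGPTL4 (up to 0.155) missed the threshold without donor 2 or donor 3, and IGFBP3 without donor 3 (0.102). INHBA stood at 2.42 CPM in untreated library 1, near the olfactory receptor level of 2.20 CPM. Of 26 immediate early genes and EGFR ligands, the transcription factor KLF6 fell 1.70-fold (adjusted p = 0.033), while EREG (log2 -0.68, adjusted p = 0.082) and FOSL1 (log2 -0.57, adjusted p = 0.16) did not pass. This list had 2 falls adjusted over the list alone, a median of -0.28 and an adjusted p of 0.023, or 0.58 with an estimated correlation. Without donor 1 its median was -0.01 and its adjusted p 0.55, and KLF6 missed the threshold without donor 2 or donor 3 (up to 0.157).

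No cell cycle gene passed the test on its own: 0 of 54 G2 and M phase genes and 0 of 43 S phase genes, over all genes or adjusted over the list alone, although 50 of 54 and 41 of 43 had positive values. At an unadjusted p under 0.05 edgeR gave 6 and 9 genes of these lists, and DESeq2 and limma-voom called 0 of either. The lowest p values belonged to BIRC5 (log2 0.61, adjusted p = 0.18), TUBB4B (0.60, 0.19) and RANGAP1 (0.37, 0.21) in the first list, and to MCM2 (0.63, 0.15), FEN1 (0.43, 0.15) and WDR76 (0.42, 0.16) in the second. The medians were 0.36 and 0.28, and the set's adjusted p was 3.1e-06 and 1.2e-05, or 0.58 and 0.55 with an estimated correlation. Donor 1 carried most of this. The G2 and M phase median was 1.09 in pair 1, 0.15 in pair 2 and -0.06 in pair 3, and without donor 1 the list had a median of 0.046 and an adjusted p of 0.43. The S phase list stayed called without donor 1 (median 0.16, adjusted p = 0.016, or 0.56 with an estimated correlation). The cholesterol synthesis list also lost its call without donor 1. Of its 25 genes 0 passed with edgeR, over all genes or adjusted over the list alone (4 at an unadjusted p under 0.05, 0 with DESeq2 or limma-voom). PMVK had a log2 fold change of 0.51 (adjusted p = 0.18) and MVD of 0.60 (0.20). The list's median was 0.23, with 0.60, 0.28 and -0.12 in pairs 1, 2 and 3. Its adjusted p was 0.0026 (0.58 with an estimated correlation) and became 0.31 without donor 1.

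Among Notch pathway genes 1 of 18 passed: LFNG, which encodes a glycosyltransferase that modifies Notch receptors, rose 2.43-fold (from 13.4 ± 1.07 to 32.9 ± 5.12 CPM, adjusted p = 0.013). The Notch target genes HES5 (log2 2.11, adjusted p = 0.051) and HEY2 (log2 0.75, adjusted p = 0.054) did not pass. Within the list, 4 rose and 3 fell adjusted over the list alone, and the list had a median of -0.01, a mean of 0.21 and a set test pointing up at an adjusted p of 0.13. Without donor 1 the Notch list was called (median 0.31, adjusted p = 0.0026, or 0.56 with an estimated correlation). Of 19 Wnt pathway genes, the ligand gene WNT4 rose 2.29-fold (from 12.4 ± 1.31 to 28.6 ± 4.76 CPM, adjusted p = 0.012), while WNT7A (log2 -0.71, adjusted p = 0.070) and ZNRF3 (log2 0.79, adjusted p = 0.082) did not pass. Adjusted over the list alone 4 rose and 1 fell, with a median of -0.01, a mean of 0.07 and a set test pointing up at an adjusted p of 0.27. Of 20 progenitor-associated transcription factors, SOX2 rose 1.63-fold (adjusted p = 0.045), FOXA1 fell 2.63-fold (from 102 ± 15.7 to 40.0 ± 14.4 CPM, adjusted p = 0.011) and SOX9 fell 1.63-fold (adjusted p = 0.038). Of its members, 4 rose and 5 fell adjusted over the list alone, with a median of -0.01 and an adjusted p of 0.70. LFNG missed the threshold without donor 2 (0.0629), FOXA1 without donor 3 (0.0610), and WNT4 (up to 0.102), SOX2 (up to 0.261) and SOX9 (up to 0.237) without donor 2 or donor 3.

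Stress and metabolic lists changed in few members. Of 29 NRF2 targets and genes of xenobiotic metabolism, 1 rose and 3 fell. The cystine transporter SLC7A11 rose 2.11-fold (adjusted p = 0.015), while HMOX1, the haem oxygenase (3.91-fold, adjusted p = 0.038), GPX2, a glutathione peroxidase (1.87-fold, adjusted p = 0.043), and ALDH1A3, a retinaldehyde dehydrogenase (log2 -1.42, adjusted p = 0.046), fell. Within the list, 1 rose and 4 fell adjusted over the list alone, with a median of -0.26 and an adjusted p of 0.011, or 0.55 with an estimated correlation, that became 0.21 without donor 1. SLC7A11 (up to 0.0670) and HMOX1 (up to 0.152) missed the threshold without donor 2 or donor 3, GPX2 without donor 1 or donor 3 (up to 0.231), and ALDH1A3 without donor 3 (0.190). HMOX1 stood at 3.28 CPM in untreated library 1, near the olfactory receptor level of 2.20 CPM. Of 21 genes of the unfolded protein response 0 passed with edgeR (4 at an unadjusted p under 0.05, 3 with DESeq2, 2 with limma-voom), with TRIB3 at 1.76 (log2, adjusted p = 0.054), DNAJB9 at -0.79 (0.075) and CHAC1 at 2.91 (0.099). Adjusted over the list alone 2 rose and 1 fell, with a median of -0.02, a mean of 0.28 and a set test pointing up at an adjusted p of 0.21, which became 0.00025 (0.65 with an estimated correlation) without donor 3. Of 30 genes of glycolysis and hypoxia 0 passed with edgeR, over all genes or adjusted over the list alone (3 at an unadjusted p under 0.05, 1 with DESeq2, 0 with limma-voom), led by NDRG1 (log2 0.71, adjusted p = 0.075), EGLN3 (-0.52, 0.16) and LDHA (0.57, 0.28), with a set adjusted p of 0.27. Of 25 p53 targets 0 passed with edgeR (6 at an unadjusted p under 0.05, 1 each with DESeq2 and limma-voom), with GDF15 at -1.85 (log2, adjusted p = 0.058), MDM2 at -0.52 (0.10) and SESN2 at 0.45 (0.15). In that list 1 fell adjusted over the list alone and the set's adjusted p was 0.17. Of 22 regulators of apoptosis and anoikis 1 fell, the death-associated kinase DAPK1 (5.74-fold, adjusted p = 0.048), which missed the threshold without donor 3 (0.142). HRK stood at -2.89 (log2, adjusted p = 0.082) and TNFSF10 at -0.86 (0.094), 3 fell adjusted over the list alone and the set's adjusted p was 0.090, or 0.035 without donor 2 (0.66 with an estimated correlation).

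Markers of other cell types were few. Of 17 leukocyte markers 4 had enough reads to be tested and 0 passed with edgeR (2 at an unadjusted p under 0.05, 1 with DESeq2, 0 with limma-voom). CD14 had a log2 fold change of -1.03 (adjusted p = 0.12), LAPTM5 of -1.33 (0.21) and CD68 of -0.83 (0.35), and 2 fell adjusted over the list alone. PTPRC, the pan-leukocyte antigen CD45, had 0 reads in each library. Of 13 endothelial and mural markers 2 were tested: CSPG4, which basal keratinocytes also express, rose 2.03-fold (adjusted p = 0.034, up to 0.168 without donor 2 or donor 3) and MCAM stood at 0.28 (log2, adjusted p = 0.29). Both rose adjusted over the list alone. Of 18 markers of rare airway and olfactory cells 1 was tested, AVIL, at -0.14 (log2, adjusted p = 0.91), and 0 passed adjusted over the list alone or with DESeq2 or limma-voom. With all donors these 3 lists had fewer than 5 tested members and were not given a set test. Without donor 1 the leukocyte list had 5 and was called lower (adjusted p = 0.0020, or 0.56 with an estimated correlation).

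**Figure D5:**
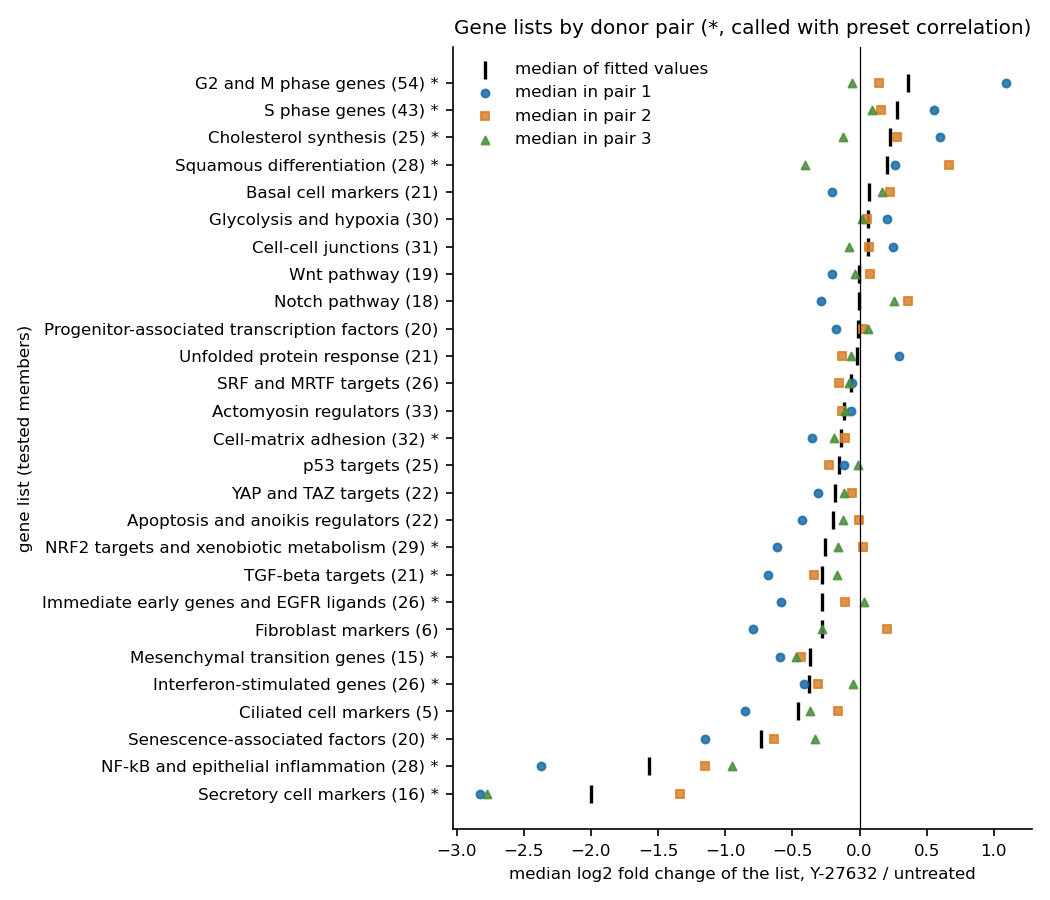
Median log2 fold change of each of the 27 gene lists given a set test, over the fitted values (black bars) and within each pair (coloured points), with the number of tested members in brackets and an asterisk at the 13 lists called with a preset correlation. Secretory markers (-2.0) and NF-kB genes (-1.57) lie lowest, and the G2 and M phase list is spread from -0.06 to 1.09 between pairs.

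Over the 27 lists, the set test with the preset correlation called 13, of which 4 pointed up and 9 down. With an estimated correlation camera called 0, with 1 list at an unadjusted p under 0.05. Fry called 1, the mesenchymal list, with 9 at an unadjusted p under 0.05. In the simulated sets camera with an estimated correlation gave the raised list an adjusted p of only 0.042. Its 0 calls here therefore do not show that the lists were unchanged. The estimated correlation between members was 0.62 in the secretory list, 0.51 in the NF-kB list and 0.84 in the G2 and M phase list, and near 0 in other called lists, such as the mesenchymal (-0.064), interferon (-0.027), cell-matrix adhesion (0.012) and TGF-beta (0.058) lists.

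Differences between donors were larger in number than those with treatment. In the same fit 914 genes differed between the 3 donors at an adjusted p under 0.05 (3630 without donor 1, 289 without donor 2 and 69 without donor 3). Of the 12244 tested genes, 42.0% had the same sign in all 3 pairs, against 25% for independent signs: 2545 higher and 2598 lower with Y-27632. Across genes, which are not independent replicates, the log2 differences of the pairs correlated at r = 0.45 (pairs 1 and 2), 0.53 (1 and 3) and 0.47 (2 and 3). Pair 1 had the widest differences, with an SD across genes of 0.78 (log2), against 0.51 and 0.48 in pairs 2 and 3. Untreated libraries 1 and 2 did not group with untreated 3. Over all counts, untreated 3 was closer to the 3 treated libraries (Spearman r of 0.976 to 0.982) than to untreated 1 (0.959) and untreated 2 (0.966). Of the 3 donors, only donor 3 had its 2 libraries closest to each other. Untreated 1 and 2 were closest to each other (0.976), above pair 1 (0.959) and pair 2 (0.974). The Spearman values include the background reads of untreated 1 and 2. On the first principal component (54.4% of the variance) untreated 1 and 2 lay at -36.1 and -51.0, with treated 2 near them at -23.4. The other 3 libraries lay between 22.1 and 52.7. The second component (21.2%) parted untreated 1 (25.5) from untreated 2 (-19.5). After the mean of each group was removed, each library correlated best with the other library of its number (r across genes of 0.33, 0.67 and 0.74 for numbers 1, 2 and 3), and 0 libraries had sex-linked transcripts that did not match the other library of their number.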

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

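One setting, the filter at the olfactory receptor level, was chosen after those reads were seen. The 258 changed genes became 475 with no low-count filter, 81 with a mean of at least 10 CPM, 555 with DESeq2, 27 at a threshold of 0.01, 40 against a 1.5-fold change and 0 without the donor block (764 at an unadjusted p under 0.05); leaving out 1 donor gave 38 to 449. The lower counts at the stricter threshold and against 1.5-fold follow from their construction, and for the others the cause was not tested. The 258 genes were all among the 555, and the 81 were all among the 258. Other scalings, limma-voom, thinning and the olfactory receptor filter gave 238 to 282. The 13 lists became 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 1 with fry. In the other settings they ran from 12 to 16. There the YAP and TAZ list was gained with RLE factors and at 10 CPM and the actomyosin and apoptosis lists at 10 CPM. The immediate early list was lost with no filter. The cause of these moves was not tested. Estimated correlations reached 0.84, but in the mesenchymal (-0.064) and interferon (-0.027) lists, which also lost their calls, they lay below the preset 0.01. In simulated data without correlation between genes, the raised list also moved from an adjusted p of 2.0e-90 to 0.042. Correlation within lists is therefore not the whole cause of the loss with an estimated correlation. In that form camera also takes its degrees of freedom from the 6 libraries and not from the genes, which raises p whatever the correlation. Genes that differ between donors, 914, became 1574 with no filter and 368 at 10 CPM, and 69 to 3630 with 1 donor left out. The share of genes with 1 sign in all pairs ran from 36.3% to 42.7% with 3 pairs, and from 60.3% to 62.8% with 2 pairs, where chance gives more.

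Of the 102 genes named by rule, 55 were called. Without the donor block 0 of them kept the call, and without donors 1, 2 and 3 the call was lost by 3, 24 and 41. It was also lost by 15 of the 47 that were tested at a mean of at least 10 CPM, 6 with no low-count filter, 3 with thinning and 1 each with limma-voom and upper quartile factors. With 1 donor left out, 7 kept it in all 3 fits (SBSN, SERPINA3, C15orf48, TNFRSF6B, FN1, VIM and SAA2). An uncalled actomyosin regulator and AVIL, also uncalled, changed sign: the first from -0.01 to 0.00395 with upper quartile factors and 0.0153 with no filter, and between -0.0547 and 0.0671 with 1 donor left out, and AVIL from -0.14 to between -0.71 and 0.365 with 1 donor left out; the cause was not tested. Scaling moved the median of all genes by at most 0.0093 (log2). Depth limits genes of a few CPM: 4878 genes with some counts were not tested.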

Other observations

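Some tests here were chosen only after the values were seen. They cover the amino acid response, retinoid, mesenchymal and G2 and M phase patterns. The filter at the olfactory receptor level and the genomic DNA test followed a look at the olfactory receptor reads. That test takes its level from untreated library 1, which had the most of those reads. A group of genes that amino acid shortage and the factor ATF4 are known to induce stood higher with Y-27632. Of 27 tested, 26 had positive values, with a median log2 fold change of 0.76 (1.03, 0.73 and 0.32 in pairs 1, 2 and 3), and 5 passed: the amino acid transporters SLC7A11 (1.08), SLC3A2 (1.29) and SLC7A1 (0.76), STC2 (1.67) and NUPR1 (0.66). Each of the 5 missed the threshold without at least 1 donor: SLC3A2 without donor 2 (adjusted p = 0.157), SLC7A11 (up to 0.0670), SLC7A1 (up to 0.193) and NUPR1 (up to 0.193) without donor 2 or donor 3, and STC2 without donor 1 or donor 2 (up to 0.222). Camera gave an unadjusted p of 4.7e-20 with the preset correlation and 0.124 with an estimated correlation, and since the list was drawn up from these data neither p is evidence for a coordinated rise, which remains open; 7 of the 27 also belong to the fixed lists.

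Genes of retinoid metabolism and response stood lower with Y-27632. Of 13 tested, 10 had negative values and 6 fell, among them the retinoic acid hydroxylase CYP26A1 (log2 -3.16, adjusted p = 0.0088), TGM2 (-3.66), DHRS3 (-2.34), RARRES3 (-1.53) and ALDH1A3 (-1.42). The median was -1.42, with -2.05, -0.79 and -1.52 in the pairs. Camera gave an unadjusted p of 2.1e-16 with the preset correlation and 0.0452 with an estimated one. Each of these 5 genes missed the threshold without at least 1 donor: CYP26A1 without donor 2 (0.0511), TGM2 (0.0518), RARRES3 (0.124) and ALDH1A3 (0.190) without donor 3, and DHRS3 without donor 1 or donor 3 (up to 0.254). The list was drawn up after some of its genes were seen to fall, so these p values are no evidence for lower retinoid signalling, which was not tested independently, and 3 of the 13 belong to the fixed lists.

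The reads on olfactory receptor and keratin-associated protein genes in untreated libraries 1 and 2 may come from genomic DNA, because these genes have intronless coding sequences that an amplicon can read from DNA. Such DNA would add a few CPM to genes of low level in those untreated libraries. Of the 187 genes lower with Y-27632, 185 lost more than 2.20 CPM, the 95th percentile of olfactory receptor genes in untreated library 1. The median loss of the 187 was 16.2 CPM. The highest olfactory receptor gene in that library stood at 5.79 CPM, and the highest keratin-associated protein gene in untreated library 2 at 10.7 CPM. Losses well above these levels argue against this source alone, and smaller losses leave it open. Of the 185, 172 stayed called without donor 1, among them the keratin-associated protein gene KRTAP2-3 (loss of 3.56 CPM). Untreated library 2 also carried such reads, so this does not part DNA from transcripts. The other 2 of the 187, COL22A1 and CXCL5, lost less and also stayed called without donor 1. They were not called without donor 2 or donor 3, with adjusted p up to 0.231 for COL22A1 and 0.163 for CXCL5. In pairs 2 and 3 both lost more than the 95th percentile of olfactory receptor genes in those untreated libraries. With genes under the olfactory receptor level left out, 11086 genes were tested and 238 were called, 231 of them among the 258.

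The fall of mesenchymal genes could reflect human fibroblasts carried over from the brushings or RNA of the mouse feeder cells. The fixed list of 17 fibroblast markers had a median of 0.236 CPM in the untreated libraries against a loss of 99.8 CPM by VIM, and 3 of the 17 reached 9.98 CPM (0.1 of that loss), COL1A1 among them (45.7 CPM, and 27.2 with Y-27632), which argues against human fibroblasts alone but leaves a part for them open. This test is the last of 3 forms, all set after the values were seen: the sum of COL1A2, COL3A1, DCN and LUM (0.347 CPM) had argued against fibroblasts, while a count over these and COL1A1 (1 of 5 at that level) had left them open, and how well the amplicons read is not known. The CPM lost by FN1, TGM2, MMP9 and MMP2 relative to VIM differed between pairs by a median of 22.8-fold, but no table holds the profile of the feeder cells or its spread between cultures, and FN1 was near the background in untreated library 1. This excludes nothing, so feeder reads, in whole or in part, and a change within the epithelial cells stay open.

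The rise of G2 and M phase genes may be a change in the cells of donor 1 alone. Without donor 1 the list's median was 0.0462, against 0.36 over the 3 pairs, and the list was not called. Whether donor 1 differs from the other donors in its response, or only in the state of its untreated culture, cannot be seen with 1 pair per donor.

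The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. For changed genes the real split gave 258 and the highest other split 0, so that 1 of the 10 splits reached 258. The donor block was kept in each split. The other splits part only 1 pair or reverse 1 pair, so a real treatment difference adds to their spread. A low count was therefore likely in them, and their 0 is not the level expected without a treatment difference. For lists called with the preset correlation, 3 of the 10 splits reached 13, the real one included, and the highest other split also gave 13. The other 3 splits that part all 3 pairs gave 0 genes each and 9, 9 and 4 lists, and the 6 that part 1 pair gave 0 genes and 7 to 13 lists.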
